A study of Mus musculus with 6 samples.

How the data were processed

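RNA sequencing was performed on neurons of the medial mammillary nucleus of male mice. Per the labels' protocols, slices were digested with papain, fluorescent cells were drawn into glass electrodes, RNA was extracted with a column kit and libraries were made with a SMARTer mRNA kit. The 6 libraries fall into 2 groups by the genotype label, 3 PV-positive (numbered 6, 7 and 8 in the titles) and 3 Drd2-positive (numbered 1, 2 and 3). The series design calls the 3 libraries of a group biological replicates; how many cells or mice went into each is not given in the sources used here. The protocol names 1.3 ug of total RNA as library input, without saying how aspirated cells gave that amount, so the quantity of material behind each library is uncertain.

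The deposited table holds FPKM values (fragments per kilobase of gene and per 1e6 fragments), made by the authors, for 55414 mouse Ensembl genes, with a gene name beside each. Per the submitters' processing notes, STAR was used, with no version, and the builds hg38, GRCh38 and mm10 are named; every gene identifier in the table is of mouse. The gene quantifier, its strand setting and the annotation release are not given in the sources used here. No name is listed for 1399 genes, and 901 names occur more than once. In GENCODE M21, the mouse annotation used here for positions and exon lengths, 52133 of the identifiers (94.1%) were found, and 95.5% of these carried the same name. Because strand use is unknown, reads of overlapping genes on opposite strands cannot be told apart: among the genes named below by the rule for single genes, exons of Nefm overlap Nefl, those of mt-Nd6 overlap mt-Nd5 and those of Lrrc3b overlap B230110C06Rik. The haemoglobin genes Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so the split of reads within each pair is uncertain.

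Low FPKM values times exon length fell on whole multiples of the worth of 1 read in each library. Among values of at most 20 reads, 97.9% to 98.7% lay within 0.01 read of a whole number, where chance gives 2%. The denominators obtained this way were 33.7, 30.0 and 23.8 for Drd2 replicates 1, 2 and 3 and 29.8, 27.7 and 28.4 for PV replicates 6, 7 and 8, in units of 1e6 fragments. At these depths 1 read in a gene of 1 kilobase is worth 0.0296 to 0.0420 FPKM. PCR copies without molecular identifiers are not independent molecules, so depth describes counting error only. An exact 0 may be a failed estimate: in PV replicate 7, 1 of 26 housekeeping genes and 1 of 79 ribosomal protein genes are listed at 0.

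Values were compared as log2(FPKM + 1), so folds of weakly expressed genes are understated. Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept (11478). PV was compared with Drd2 by limma 3.58.1 (R 4.3.3), with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 folds are PV minus Drd2. Of 33 gene lists, 30 had at least 3 tested members and were tested with camera at a preset correlation of 0.01; camera with an estimated correlation, camera on ranks and fry were alternatives. Members were also adjusted over the list alone. Pvalb and Drd2 were in none of the lists. Single values per library were compared by an exact permutation test, 2-sided, whose smallest possible p for 3 against 3 is 0.1.

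Design, lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Pvalb and Drd2; per direction, up to 12 genes with the largest fold among those past the threshold with an absolute log2 fold of at least 1, no overlap between groups and a mean of at least 5 FPKM in the higher group, leaving out predicted or unnamed genes; where fewer than 6 pass in a direction, the 6 with the smallest p; and up to 4 members per list with the smallest p. Other genes named were chosen after their values were seen, and are marked so.

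Alternatives were other pseudocounts, filters, scalings (TPM, median of ratios, quantile), variance models, array weights and leaving out each library. Added after the data were seen were limma voom on the recovered reads, rescaling over nuclear protein-coding genes, and leaving out PV replicate 7 and Drd2 replicate 3 together. Leaving out each library was first run with genes filtered again. Keeping the genes tested on all 6 libraries was chosen after those counts were seen, and is the version given unless filtering again is stated. The gene test was tested on simulated data for PV against Drd2 over 11478 genes with 200 changed. It recovered 60%, 94%, 98% and 100% of genes changed by 2, 3, 4 and 5 on the log2 scale. Of 185 calls 9 were false, and at most 1 gene was called in 10 sets with no change. Changed genes were drawn only from those with a mean log2 value above 4. Noise was independent between genes, with a spread drawn around a smoothed curve. Recovery in the real data may be lower: Syt5, with a log2 fold of -4.71, did not pass (limma adjusted p = 0.0653). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.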

Results

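The transcriptomes of 2 neuron classes of the medial mammillary nucleus, a hypothalamic cell group, were compared: neurons labelled through PV, the calcium-binding protein parvalbumin, and neurons labelled through Drd2, the D2 dopamine receptor. Each class had 3 libraries, with FPKM denominators of 23.8 to 33.7 in units of 1e6 fragments. Genes at 1 FPKM or more numbered 12398, 8610 and 10293 in PV replicates 6, 7 and 8 and 11110, 12233 and 12212 in Drd2 replicates 1, 2 and 3; the group means did not separate (exact permutation p = 0.4). Across tested genes, library pairs within PV correlated at a mean r of 0.721, pairs within Drd2 at 0.802 and pairs between the groups at 0.702. Pairs between the groups ranged from 0.632 to 0.787 and pairs within PV from 0.690 to 0.771. PV replicate 6 correlated with the Drd2 libraries at 0.759 to 0.787 and with PV replicate 7 at 0.702. Mitochondrial genes made up 21.3% ± 10.9 of the FPKM total in PV and 4.23% ± 0.839 in Drd2 (SD, n = 3 each), a difference of 17.1 percentage points with no overlap (exact permutation p = 0.1, the smallest possible). As a share of recovered reads they made up 12.1%, 17.6% and 4.68% in PV replicates 6, 7 and 8 and 1.74%, 2.34% and 1.67% in Drd2 replicates 1, 2 and 3. Of the FPKM total, mitochondrial ribosomal RNA made up a mean of 10.1% in PV and 1.39% in Drd2. Protein-coding mitochondrial genes made up 10.6% and 2.77%.

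**Figure D1:**
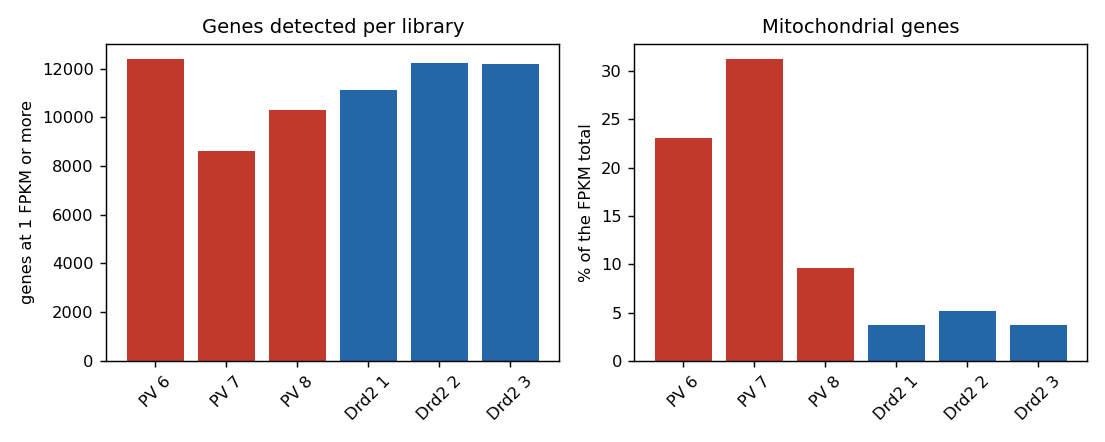
Bars show, for each library, the number of genes at 1 FPKM or more and the share of the FPKM total from mitochondrial genes, in percent. PV replicate 7 has the fewest genes, 8610, and the highest mitochondrial share, 31.3%, while the Drd2 libraries lie between 3.74% and 5.20%.

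The first comparison checked the labels. Pvalb (ENSMUSG00000005716, mm10 chromosome 15, 78191114 to 78206400) was at 349, 482 and 563 FPKM in the PV libraries and at 10.4, 22.5 and 99.5 FPKM in Drd2 replicates 1, 2 and 3, with a log2 fold of 3.93 ± 0.69 (SE). Drd2 (ENSMUSG00000032259, chromosome 9, 49340627 to 49408177) was at 42.7, 55.0 and 7.74 FPKM in the Drd2 libraries and at 0.0132 FPKM in PV replicate 6, and was listed at 0 in the other PV libraries, with a log2 fold of -4.79 ± 0.81 (SE). Neither gene overlapped between the groups. Neither passed the threshold in limma, with an adjusted p of 0.0501 for both. Drd2 replicate 3 held the most Pvalb and the least Drd2 of its group.

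The second question was which genes set the classes apart. By limma, 30 of 11478 genes passed, 25 higher in Drd2 and 5 higher in PV, and 1468 had an unadjusted p under 0.05, of which 1121 were higher in Drd2. The median log2 fold of all tested genes was -0.28. It was -0.50 after rescaling to TPM, -0.12 with median-of-ratios scaling and 0.05 with quantile normalization, so the medians of lists past the threshold are also given relative to it. With quantile normalization 46 genes were higher in Drd2 and 22 in PV (32.4% of calls, against 16.7%).

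Genes higher in Drd2 neurons included the calcium-binding proteins Calb1, Hpcal1 and Necab2. Calb1, the calcium buffer calbindin, was at 222 ± 40.4 FPKM in Drd2 and 7.73 ± 9.53 in PV (SD, n = 3 each), a log2 fold of -5.36 ± 0.79 (SE; limma adjusted p = 0.0384). Hpcal1, a neuronal calcium sensor, was at 277 ± 26.9 against 21.1 ± 11.5 FPKM and fell by 3.78 ± 0.45, and Necab2, a calcium-binding protein of neurons, was at 137 ± 19.4 against 7.03 ± 8.21 FPKM. Gpr83, a G-protein-coupled receptor, was at 105 ± 58.8 FPKM in Drd2 and 3.51 ± 1.65 in PV. Ngb, the oxygen-binding neuroglobin, was at 106 ± 49.7 against 2.45 ± 2.21 FPKM. Gng4, a G-protein gamma subunit, was at 24.5 ± 2.59 against 0.564 ± 0.756 FPKM. Rsph9, a radial spoke protein of motile cilia, was at 69.3, 39.6 and 25.6 FPKM in the Drd2 libraries and was listed at 0 in all 3 PV libraries.

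The other genes the rule took on this side had log2 folds from -5.28 to -4.41. They were Trp53i11, the retinoid receptor Rxrg, the lipid phosphatase Plpp2, the sodium-iodide symporter Slc5a5, Lrrc3b, the class I gene H2-Q2 and the immune surface protein Cd83. H2-Q2 belongs to a multigene family, so its reads may be shared with its relatives and its level is uncertain. Among calls outside the rule, chosen after their values were seen, Zcchc12 was at 306 ± 19.1 FPKM in Drd2 and 28.7 ± 7.08 in PV, the metalloproteinase inhibitor Timp2 at 113 ± 20.3 against 16.6 ± 1.90, and Tafa1, a secreted protein of the brain, at 75.2 ± 9.44 against 5.84 ± 1.91.

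On the PV side, the calls were 2 neurofilament genes and 3 haemoglobin genes. Nefh, the heavy neurofilament chain (chromosome 11, 4938754 to 4948064), was at 79.1 ± 4.04 FPKM in PV and 12.7 ± 1.20 in Drd2, a log2 fold of 2.55 ± 0.39 (SE; limma adjusted p = 0.0384). Nefm, the medium chain (chromosome 14, 68082590 to 68124846), was at 96.9 ± 30.7 against 11.9 ± 4.52 FPKM, a log2 fold of 2.93 ± 0.48 (limma adjusted p = 0.0497). The sixth gene by p on this side, mt-Nd6, was at 2418 ± 1290 against 213 ± 113 FPKM and did not pass (limma adjusted p = 0.0501).

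**Figure D2:**
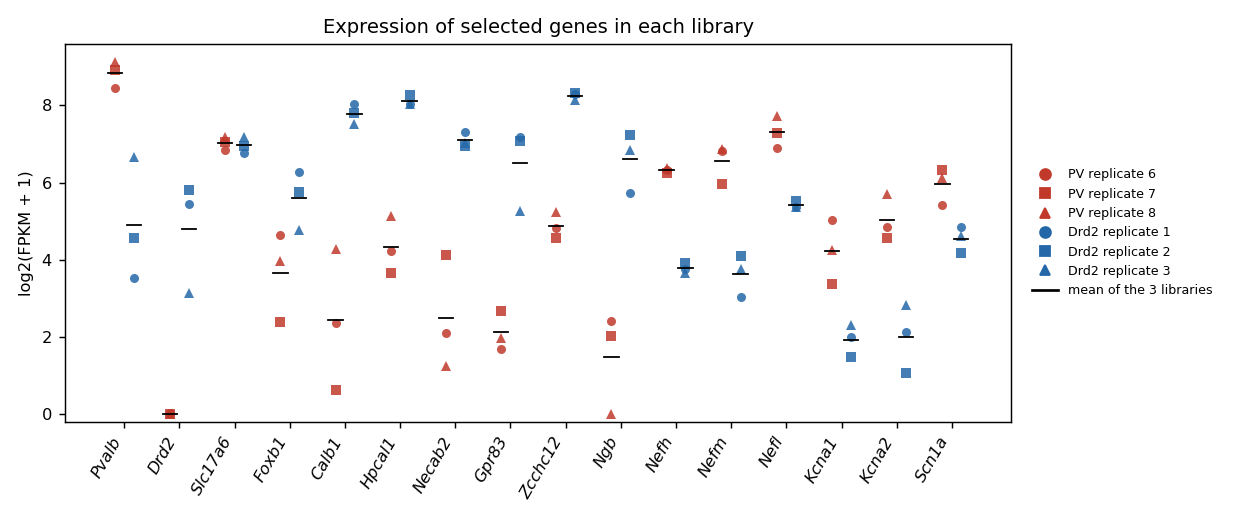
Points give log2(FPKM + 1) of 16 genes in each library, and lines the mean of 3 libraries. Calb1, Hpcal1, Necab2, Zcchc12 and Ngb separate the groups in 1 direction and Nefh and Nefm in the other, Slc17a6 lies at the same level in both, and Pvalb of Drd2 replicate 3 lies nearest to the PV libraries.

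**Figure D3:**
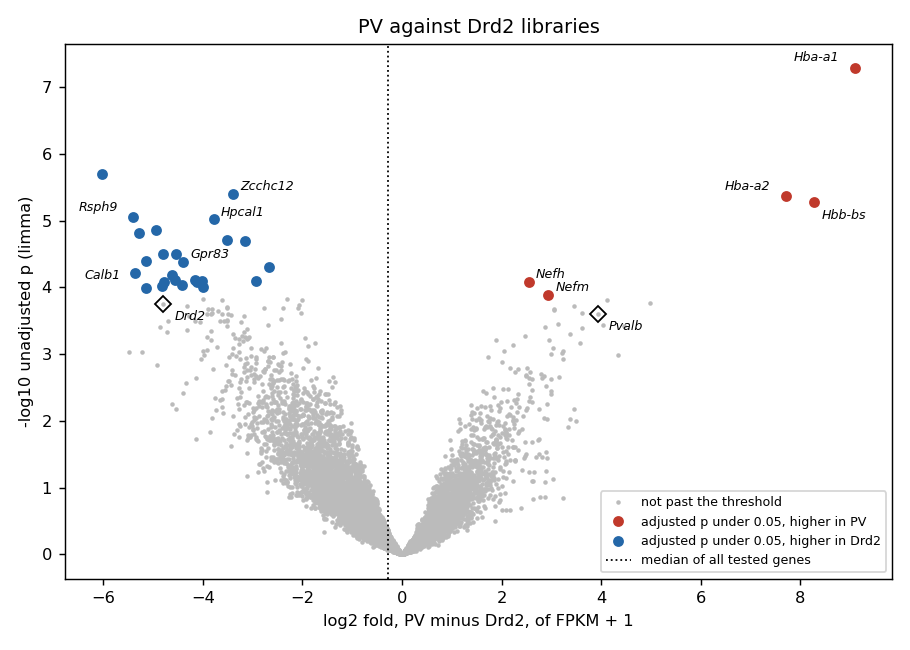
Each point is 1 of 11478 genes, with its log2 fold (PV minus Drd2, of FPKM + 1) against -log10 of the unadjusted limma p. The 25 genes past the threshold on the Drd2 side and the 5 on the PV side are coloured, and the diamonds mark Pvalb and Drd2, which lie just under it.

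These calls depended on which libraries and filter were used. With no filter on low values 0 genes passed in limma (1509 at an unadjusted p under 0.05), with a pseudocount of 0.1 FPKM 4 did, and without Drd2 replicate 1, 2 or 3 only 2, 3 and 1 did, none of them higher in Drd2, while 56 passed without PV replicate 6. All 30 calls kept their sign in every setting in which they were tested. They were picked from these same libraries as past the threshold, so a kept sign is no separate evidence.

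Genes of fast-spiking neurons were higher in PV. Of 14 tested members 13 had a fold above 0, 2 passed over all genes (Nefh and Nefm) and 7 adjusted over the list alone; the median log2 fold was 1.26, 1.54 above that of all genes (camera adjusted p = 1.55e-10; adjusted p = 0.196 with an estimated correlation). Among members that did not pass over all genes, the potassium channel Kcna2 was at 33.7 ± 14.9 FPKM in PV and 3.51 ± 2.52 in Drd2, Kcna1 at 19.7 ± 11.3 against 2.90 ± 1.07, and the light neurofilament chain Nefl at 161 ± 47.3 against 41.8 ± 2.70.

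Neuropeptide receptors were lower in PV. All 9 tested members had a fold below 0, 1 passed over all genes (Gpr83) and 2 adjusted over the list alone, with a median of -1.69, -1.41 relative to that of all genes (camera adjusted p = 0.00199; adjusted p = 0.293 with an estimated correlation). The melanin-concentrating hormone receptor Mchr1 had a log2 fold of -3.28 and the cholecystokinin receptor Cckbr of -1.69, neither past the threshold over all genes, and Mchr1 passed adjusted over the list alone. The list median ran from -3.71 with voom to -0.57 with no filter on low values. Of 18 calcium-binding genes, 3 fell (Calb1, Hpcal1 and Necab2), also adjusted over the list alone. Pvalb, which also encodes a calcium-binding protein and was higher in PV (log2 fold 3.93), was left out of the list. The list missed the threshold in camera (adjusted p = 0.0880). It passed in camera with a pseudocount of 5 FPKM (0.0389), no filter (0.0319), quantile normalization (0.0250), without PV replicate 8 (0.0339) and, with genes filtered again, without Drd2 replicate 1 (0.0420) or PV replicate 8 (0.0446), and adjusted p ran up to 0.417 over all alternatives. Fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.0446.

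Both classes held glutamatergic and mammillary genes. The vesicular glutamate transporter Slc17a6 was at 130 ± 15.1 FPKM in PV and 125 ± 18.1 in Drd2. None of the 9 tested glutamatergic genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.492). Of 7 mammillary transcription factors, Foxb1 had a log2 fold of -1.94 and Nkx2-4, at 4.62, 9.66 and 1.48 FPKM in the Drd2 libraries, was listed at 0 in all 3 PV libraries, neither passing over all genes, and 1 passed adjusted over the list alone (camera adjusted p = 0.509). The GABA-synthesis gene Gad2 was at 5.07 ± 4.91 FPKM in PV and 0.0283 ± 0.0491 in Drd2 and did not pass, and the gabaergic list did not either (camera adjusted p = 0.160), with 3 of its 4 tested members past the threshold adjusted over the list alone.

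Transcripts of mitochondrial respiration were higher in PV by camera at the preset correlation. By fry neither the nuclear list nor the list encoded in mitochondrial DNA passed (adjusted p = 0.307 each). Of 85 nuclear oxidative phosphorylation genes 67 had a fold above 0, with a median of 0.64, 0.91 above that of all genes (camera adjusted p = 7.33e-14; adjusted p = 0.471 with an estimated correlation). None passed alone, over all genes or adjusted over the list alone; Atp5g1, a subunit of ATP synthase, had a log2 fold of 1.38 and Ndufc1, of complex I, of 1.80. The median deviation of these genes from that of all genes was -0.33 in PV replicate 6, 1.18 in PV replicate 7 and 0.47 in PV replicate 8, and -0.24, -0.72 and -0.64 in Drd2 replicates 1, 2 and 3, so PV replicate 6 lay within the Drd2 range. Without PV replicate 7 the list median lay 0.59 above that of all genes. Of 13 genes encoded in mitochondrial DNA, 12 had a fold above 0, none passed over all genes and 7 did adjusted over the list alone (median 1.48, 1.76 relative to that of all genes; camera adjusted p = 5.14e-08; adjusted p = 0.389 with an estimated correlation). With quantile normalization the median was 0.61, with a median of all genes of 0.05 (adjusted p = 0.00259, from 4.44e-12 to 0.389 over all alternatives). Reads of several of them may be shared with nuclear copies.

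Immediate-early genes, which rise with activity and handling, were lower in PV. Of 18 tested members 16 had a fold below 0 and none passed over all genes or adjusted over the list alone, with a median of -1.77, -1.49 relative to that of all genes (camera adjusted p = 0.00106; adjusted p = 0.473 with an estimated correlation). Fos was at 610, 1010 and 155 FPKM in Drd2 replicates 1, 2 and 3 and at 96.5, 1.78 and 119 in PV replicates 6, 7 and 8. Of 19 stress-response genes 15 had a fold below 0 and 5 passed adjusted over the list alone, none over all genes (median -0.84, -0.56 relative to that of all genes; camera adjusted p = 0.0467; adjusted p = 0.389 with an estimated correlation). That call was lost with median-of-ratios scaling (adjusted p = 0.0942), rescaling over nuclear protein-coding genes (0.132), at least 5 FPKM in 3 libraries (median -0.50, adjusted p = 0.265), a pseudocount of 0.1 FPKM (0.0531), voom (0.0946) and camera on ranks (0.109). It was also lost without Drd2 replicate 2, Drd2 replicate 3, PV replicate 6 or PV replicate 8 (0.107, 0.0709, 0.301 and 0.0634). With genes filtered again it was lost without Drd2 replicate 1 (0.0645), Drd2 replicate 2 (0.177), Drd2 replicate 3 (0.187) or PV replicate 6 (0.237) and passed without PV replicate 8 (0.0467), and adjusted p ran from 0.00735 to 0.389 over all alternatives.

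Markers of other cell types varied between single libraries, and among the lists tested with the main filter haemoglobin separated the groups most clearly. The haemoglobin genes Hba-a1, Hbb-bs and Hba-a2 had log2 folds of 9.09 ± 0.60, 8.28 ± 0.91 and 7.72 ± 0.83 (SE; limma adjusted p = 0.000598, 0.0121 and 0.0121). Their sum with Hbb-bt was 2315 ± 1366 FPKM in PV and 3.95 ± 6.55 in Drd2 (SD, n = 3 each). The blood list passed (4 tested members; median 8.00, 8.28 relative to that of all genes; camera adjusted p = 2.92e-11; adjusted p = 0.169 with an estimated correlation), and 3 of them passed adjusted over the list alone. Microglial genes were higher in PV by the list test (16 members, none past the threshold over all genes or adjusted over the list alone; median 1.55, 1.83 relative to that of all genes; camera adjusted p = 0.000776; adjusted p = 0.570 with an estimated correlation), but their sum was highest in a Drd2 library: 4306 FPKM in Drd2 replicate 3, against 106 and 227 in Drd2 replicates 1 and 2 and 2051, 1150 and 631 in PV replicates 6, 7 and 8. The call was lost without Drd2 replicate 1 (median 0.12, adjusted p = 0.240) or PV replicate 6 (median 1.02, adjusted p = 0.0555; 1.03 and 0.0419 with genes filtered again), and the median was 2.81 without Drd2 replicate 3; adjusted p ran from 4.44e-15 to 0.617 over all alternatives.

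Oligodendrocyte genes were lower in PV (15 members, none past the threshold over all genes and 1 adjusted over the list alone; median -1.77, -1.49 relative to that of all genes; camera adjusted p = 0.0465; adjusted p = 0.742 with an estimated correlation). Myelin transcripts were uneven in the Drd2 group: Mog was at 51.5, 254 and 7.85 FPKM in Drd2 replicates 1, 2 and 3. The sum of the list overlapped between the groups, at 531, 1687 and 96.3 FPKM in these and 354, 366 and 80.5 in PV replicates 6, 7 and 8. The call was lost after rescaling to TPM (adjusted p = 0.121), with a pseudocount of 0.1 FPKM (0.185), at least 5 FPKM in 3 libraries (0.139), voom (0.528) and fry (0.557). It was also lost without Drd2 replicate 1 (median -1.08, adjusted p = 0.169), Drd2 replicate 2 (median -0.97, adjusted p = 0.593), PV replicate 6 (0.0920) or PV replicate 8 (0.438), and adjusted p ran from 2.61e-09 to 0.756 over all alternatives. The monoaminergic and cholinergic list, with 3 tested members, was higher in PV (median 1.14, 1.42 relative to that of all genes; camera adjusted p = 0.0176; adjusted p = 0.403 with an estimated correlation), none past the threshold over all genes and 1 adjusted over the list alone; the transcription factor Nr4a2 was at 2.48 ± 1.66 FPKM in PV and 0.0438 ± 0.0758 in Drd2. That call was lost without Drd2 replicate 1, PV replicate 6 or PV replicate 7 (adjusted p = 0.0618, 0.0555 and 0.124) and with array weights (0.0533), the median was 1.84 without PV replicate 8, and adjusted p ran from 0.00263 to 0.403 over all alternatives. Astrocyte genes did not differ past the threshold (13 members; camera adjusted p = 0.895). Precursors of oligodendrocytes, vascular cells and ependymal cells had 1 tested marker each, too few for a test with the filter used. With no filter, the list of 7 markers of oligodendrocyte precursors was higher in PV by the list test (camera adjusted p = 0.0130, and 0.0537 for 3 markers with a mean of at least 1 FPKM). Only 4 of the 7 reached 1 FPKM in any library, and Lhfpl3 made up nearly all of their sum in PV replicate 7. The vascular and ependymal lists did not pass in camera with no filter (0.142 and 0.521). The precursor markers summed to 21.2, 10.7 and 25.4 FPKM in PV replicates 6, 7 and 8 and to 1.67, 4.35 and 2.66 in Drd2 replicates 1, 2 and 3, with C1ql1 (14.2 FPKM), Lhfpl3 (10.6) and Neu4 (16.7) the most abundant in PV replicates 6, 7 and 8.

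**Figure D4:**
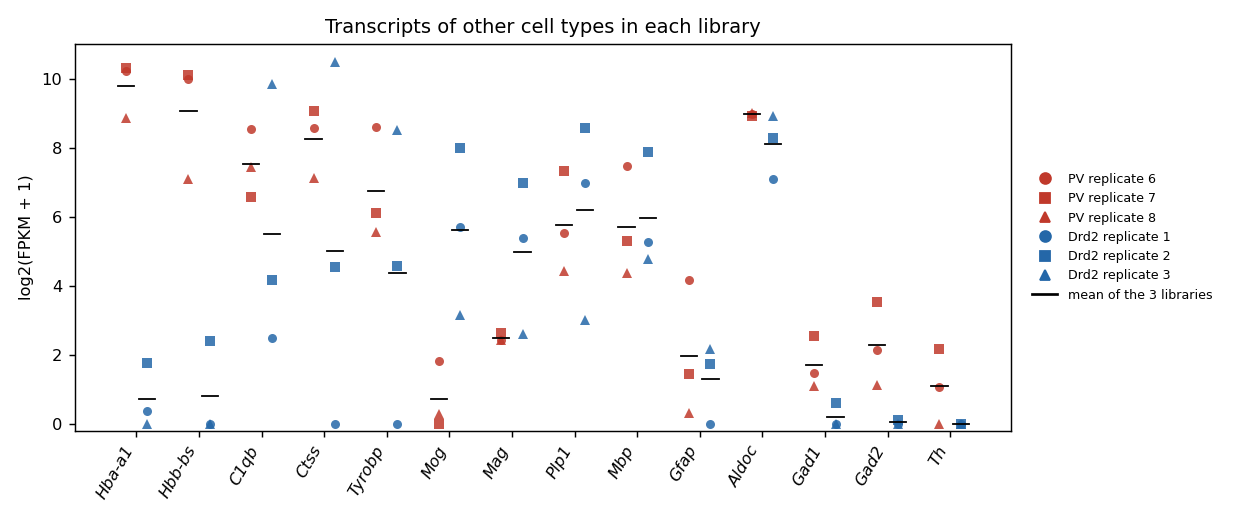
Points give log2(FPKM + 1) in each library for markers of red blood cells, microglia, oligodendrocytes, astrocytes and GABA or catecholamine neurons, and lines the mean of 3 libraries. Haemoglobin separates the groups, the microglial genes C1qb and Ctss are highest in Drd2 replicate 3, and Mog and Mag are highest in Drd2 replicate 2.

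The other lists did not pass in camera with the settings used. Adjusted p was 0.0880 for dopamine signalling, 0.144 for potassium channels, 0.273 for neuropeptides and for metabotropic glutamate receptors, 0.509 for GABA and glycine receptors and for ionotropic glutamate receptors, and 0.547 for sodium, calcium and HCN channels. It was 0.614 for adhesion and axon guidance, 0.635 for apoptosis and p53 genes, 0.835 for monoamine and acetylcholine receptors, 0.859 for synaptic vesicle release and for perineuronal net genes, 0.862 for G-protein signalling and for pan-neuronal genes, and 0.955 for ribosomal proteins. Of their genes, only the G-protein subunit Gng4 passed over all genes. Adjusted over the list alone, 6 synaptic vesicle genes passed, 3 in each direction, as did 2 potassium channels and 2 monoamine or acetylcholine receptors, 1 in each direction. So did 1 gene each of neuropeptides and G-protein signalling, higher in Drd2, and 1 each of ionotropic glutamate receptors, adhesion and pan-neuronal genes, higher in PV, and none of the others. Some of these lists passed in camera under alternatives: potassium channels (adjusted p = 0.00570) and sodium, calcium and HCN channels (0.0393) with at least 5 FPKM in 3 libraries, potassium channels also without Drd2 replicate 2 (0.0440) or PV replicate 7 (0.0374) with genes filtered again, ribosomal proteins without PV replicate 7 (0.00329), dopamine signalling without PV replicate 8 (0.0309) and the gabaergic list with no filter (0.0281). Over all alternatives, adjusted p of these 5 lists ran up to 0.909, 0.952, 0.989, 0.552 and 0.473. In 8 of the 30 lists, none of them past the threshold, the median, mean and test differed in sign.

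**Figure D5:**
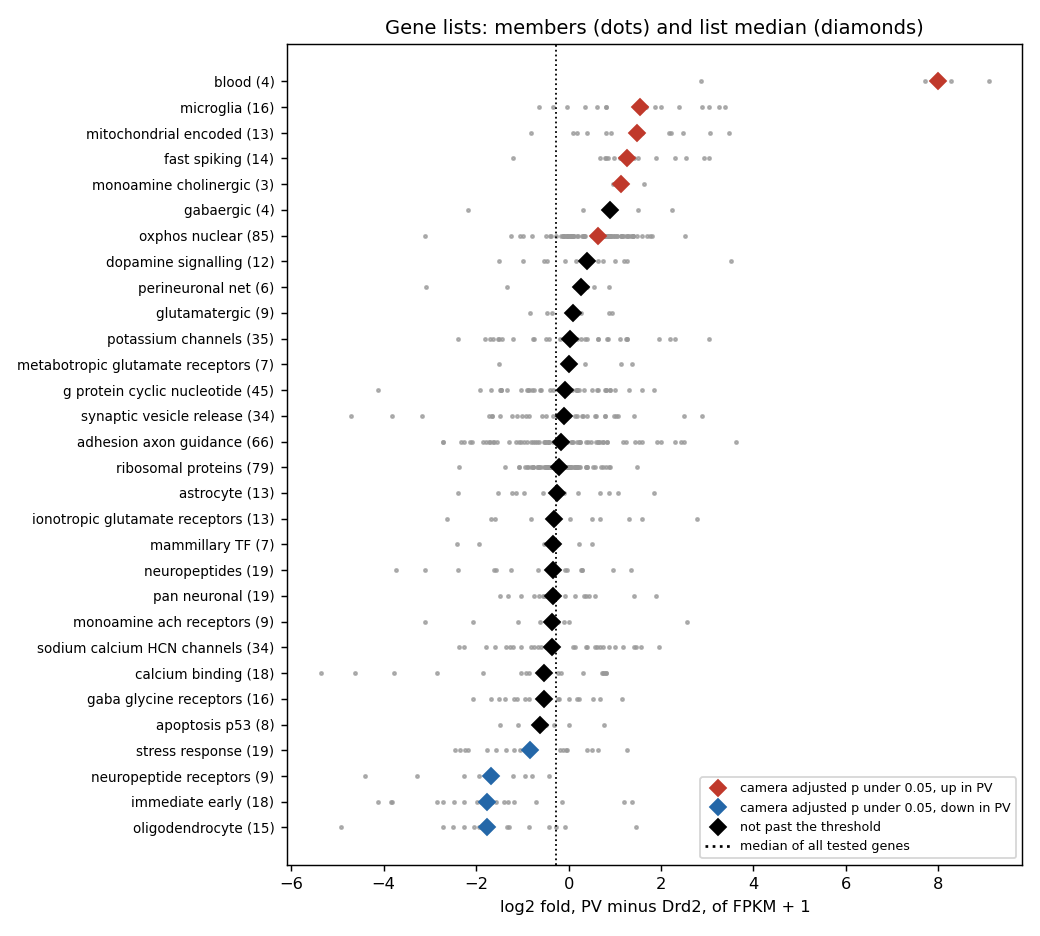
Each row is a gene list with its number of tested members; dots are members and diamonds list medians of the log2 fold (PV minus Drd2, of FPKM + 1). The dotted line is the median of all tested genes, -0.28, and coloured diamonds are the 10 lists past the camera threshold.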

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

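Voom, nuclear rescaling, the pair of left-out libraries and the leave-one-out fits that kept the genes tested on all 6 libraries were chosen after the data were seen. The cause of each change below was not tested. The 30 calls (5 higher in PV, 25 in Drd2) became 4 (1 and 3) with a pseudocount of 0.1 FPKM and 68 (13 and 55) with 5 FPKM. They became 0 (0 and 0) with no filter and 69 (17 and 52) with a mean of at least 1 FPKM. Quantile normalization gave 68 (22 and 46), robust moderation 53 (11 and 42) and array weights 105 (24 and 81). Without an intensity trend 46 passed (40 higher in Drd2). TPM gave 3 higher in PV, and voom on recovered reads 15 higher in Drd2. Rescaling over nuclear protein-coding genes gave 15 (11 higher in Drd2), and leaving out PV replicate 7 and Drd2 replicate 3 gave 18 (13 higher in Drd2).

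Leaving out each library was first run with the filter applied again to the other 5 libraries. That gave 3 to 57 calls (3 to 7 higher in PV, 0 to 54 higher in Drd2), but only 19 of the 30 calls were still tested without a Drd2 library. After these counts were seen, the genes tested on all 6 libraries were kept instead, which gave 1 to 56 calls (1 to 7 higher in PV, 0 to 52 higher in Drd2). Without Drd2 replicate 1 or 2 neither version gave a call on the Drd2 side. No paired analysis was possible because the replicate numbers 6 to 8 and 1 to 3 share none. No covariate was fitted. If the libraries of each class were prepared apart, class and preparation cannot be told apart for any difference given here, haemoglobin and the mitochondrial share included.

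Pvalb and Drd2 missed the threshold by little and kept their direction in all settings in which they were tested. Neither overlapped between the groups, so leaving out a library could not reverse them. The Pvalb log2 fold, PV against Drd2, passed with a pseudocount of 5 FPKM (3.70), a mean of at least 1 FPKM (3.93), median of ratios (4.12), quantile normalization (4.07), array weights (4.13), voom (4.20) and without the pair of libraries (4.76). Leaving out 1 library gave a Pvalb log2 fold of 3.23 to 4.80, past the threshold only without Drd2 replicate 3 after refiltering. The Drd2 log2 fold, PV against Drd2, passed with a mean of at least 1 FPKM, no trend or robust moderation (-4.79 each), TPM (-6.22), quantile normalization (-4.46), array weights (-5.08) and without the pair (-5.62). The adjusted p over all alternatives ran from 0.0208 to 0.513 for Pvalb and from 0.0244 to 0.340 for Drd2.

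The count of 10 gene lists past the threshold became 0 with an estimated correlation and 6 to 10 with 1 library left out (7 to 11 with genes filtered again). Fry, which tests a list against no change, gave 5 lists, among them the calcium-binding list, which is not among the 10. Without the pair of libraries, 2 named genes that had not passed changed sign: the log2 fold of Ddc was -0.0450 and the log2 fold of Trp53 0.38. The share of FPKM from mitochondrial genes, PV minus Drd2, stayed above 0 in all 7 alternatives, all chosen after the data were seen, from 9.54 points as a share of recovered reads to 22.9 without PV replicate 8. The shares did not overlap between the groups, so leaving out a library could not reverse their difference. Depth limits the lowest genes: 1 read in 1 kilobase is 0.0296 to 0.0420 FPKM.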

Other observations

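The tests of haemoglobin, of Pvalb in Drd2 replicate 3, of rescaling and of PV replicate 7 were chosen after the results were seen. The splits for the counts of genes and lists past the threshold and the test of gene length were not. A set of genes was listed at 0 in all libraries of 1 class and at 5 FPKM or more in all libraries of the other. There were 13 such genes on the Drd2 side and 3 on the PV side, and the highest count in another split of the 6 libraries was 6. Genes above 0 numbered 12873 in PV replicate 7, against 18506 and 15872 in PV replicates 6 and 8 and 15696 to 17559 in the Drd2 libraries. Whether missed detection adds to the count on the Drd2 side was not tested. On the Drd2 side they included Rsph9 and Enkur, both of motile cilia or sperm tails, the peptide neuromedin U (Nmu; 34.5, 5.47 and 9.02 FPKM in replicates 1, 2 and 3), the sialyltransferase St8sia2, the phosphatase inhibitor Ppp1r17 and Gchfr, a regulator of tetrahydrobiopterin synthesis. On the PV side Sntg2, a syntrophin, was at 8.28, 7.30 and 7.67 FPKM. These genes were chosen after their values were seen. Of these, Rsph9 alone among the genes named here passed the threshold in limma.

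Some receptor and synaptic genes that did not pass over all genes went both ways, and the 6 named here passed adjusted over their list alone. Chrm3, a muscarinic receptor, was at 9.20 ± 2.53 FPKM in Drd2 and 0.165 ± 0.162 in PV (SD, n = 3 each), while the adrenergic receptor Adra1b was at 1.81 ± 1.58 against 14.5 ± 5.65. Stx1a, a syntaxin of vesicle release, was at 20.3 ± 4.50 against 0.653 ± 0.986 FPKM, and Rab3b at 63.1 ± 39.4 against 5.49 ± 1.85. The AMPA receptor subunit Gria3 was at 0.0625 ± 0.0955 against 7.40 ± 5.69 FPKM and the protocadherin Pcdh20 at 0.863 ± 0.759 against 22.0 ± 11.1.

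Haemoglobin transcripts were higher in PV. Scaling is argued against, since the lowest of the 3 folds over 4 scalings was 7.71 on the log2 scale. Reads moved between near-identical copies, within the alpha pair or within the beta pair, are argued against too, since the lowest PV haemoglobin sum was 64.5 times the highest Drd2 sum. RNA of red blood cells may be a source: of 10 erythroid genes chosen 9 were in the table, and 0 of them reached 1 FPKM in at least 2 PV libraries and no Drd2 library, but Epb42 (1.67 FPKM in PV replicate 8; Alas2 was at 3.56, 0.466 and 0 in PV replicates 6, 7 and 8) came to 0.224% of the haemoglobin sum, above the 0.1% set to exclude it, so red blood cells and expression in the neurons cannot be told apart.

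Pvalb in Drd2 replicate 3 reached 18.5% of the way from the other Drd2 libraries to the PV mean. PV neurons mixed into that library may account for it, but the test decides nothing: over 56 genes higher in PV without it, the median share was 16.2% (95% bootstrap interval 3.46% to 43.5%), while single shares ran from -13.6% to 534% and 17 were at 0 or below. Without the microglia list, of which C1qc, C1qb and Ctss had the highest shares, the median over 50 genes was 13.8% (0.903% to 35.6%). Very high shares remained among these 50 genes, such as Arhgdib (265%), Fcer1g (252%) and Lyz2 (138%), the last from the blood list. The microglia list summed to 4306 FPKM in this library, against 106 and 227 in Drd2 replicates 1 and 2. RNA of microglia or related cells may raise these shares too, which was not tested, so leaving out the list may not free the median of it. Other genes were near 0 or below, such as Nefl (-2.35%), Pcdh20 (3.96%), Hba-a1 (-0.138%) and mt-Nd2 (-8.47%). The haemoglobin sum was 0 FPKM in this library, but the source of haemoglobin in the PV libraries is itself open. Against that, 27 of the 56 genes had a share at or above that of Pvalb, among them Syn2 (32.0%). The median over 50 genes therefore decides nothing either. Nefh had a share of -2.37% and Nefm of 0.903%, and the median level of 148 genes higher in Drd2 was 60.6% (52.2% to 65.7%) of that in replicates 1 and 2, while Drd2 itself was at 15.8%. Mixing and a difference of that library's neurons cannot be told apart, since the shares of the genes differ too widely.

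Nuclear oxidative phosphorylation genes were higher in PV as a list. Rescaling over nuclear protein-coding genes left their median 0.949 above that of all genes, against 0.914 before. It moves all genes of a library alike, so this test could not have come out otherwise. Dilution by mitochondrial RNA would lower nuclear genes in PV, where the mitochondrial share was higher (21.3% against 4.23% of FPKM), and all of them alike. The list median of 0.64 before rescaling, above that of all genes, argues against dilution as its source. A gain of all genes with short exon length is argued against: lists matched on exon length and expression had a median of -0.26, against 0.63 for these genes. Their median exceeded 100% of 10000 matched lists. Members of the list vary together (estimated correlation 0.40) and matched genes were drawn singly, so that share does not measure variation between libraries. Lengths were of all exons of a gene, so the length of the expressed transcript was not tested. Without PV replicate 7 the list median still lay 0.592 above that of all genes, but PV replicate 6 was not raised (-0.33), and with an estimated correlation the list did not pass. A difference between the classes stays open and is a hypothesis only.

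Whether chance can be excluded was asked by regrouping the libraries. Of the 10 splits, 1 (the real one) gave 30 genes and the highest other gave 0, and 1 (the real one) gave 10 lists and the highest other gave 6. The 10 splits are too few for a share under 0.05.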
